A study of Mus musculus with 8 samples.

How the data were processed

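Exosomes were isolated from mouse amniotic fluid by size-exclusion chromatography, with fractions 7 to 9 pooled, per the labels' protocols. Per the same protocols, LPS was injected into the abdomen on day 14 of pregnancy, and Cy3-labelled material was prepared from 0.5 μg of RNA per sample with a kit for linear amplification. The labels call this material cRNA, a product made from mRNA, so how the miRNAs themselves were labelled is not given in the sources used here. Hybridization, washing and scan settings are not given in the sources used here. The labels give day 17 as the stage of every sample, and they do not say how the cesarean controls were treated or whether replicates are separate animals. The 8 samples were grouped by their labels into 4 LPS preterm births and 4 cesarean sections.

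The spot intensity values were read per the file headers with Agilent Feature Extraction 10.7.1.1 as linear, background-subtracted signals without normalization between arrays, while the submitters' processing notes name version 9.1. Each file holds 58594 spots, of which 56430 carry miRNA probes and 2164 are controls. The deposited value table holds log2 values that the authors had normalized between arrays, with column medians from 2.14 to 2.15, and its normalization method, background correction and summary per miRNA are not given in the sources used here. Its columns were checked against the scanner files over 393 miRNAs, and each column correlated best with the file of its own array (r from 0.967 to 0.986). The table served as an alternative and the scanner files as the basis of all other values.

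Control spots and spots with outlier or non-uniformity marks from the scanner software were left out, which removed between 3.00% and 3.48% of the miRNA spots of an array. No miRNA spot was saturated. A probe counted as well above background on an array if at least a share of 0.5 of its kept spots did so by the scanner software. Signals were divided per array by the 75th percentile over the 618 probes detected on all arrays and put on a common scale. Probe means were then raised to a floor of 13.5, the median over arrays of the lowest signal well above background, and put on the log2 scale, where the floor is 3.75. The brightest probe over all arrays stood for each miRNA. Tested were 470 of 1881 miRNAs, those well above background on at least 3 of the 4 arrays of either group.

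Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, LPS minus cesarean, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. For a miRNA not well above background on any array of a group, only a lower bound on the fold, taken against the floor, is given. The number of detected miRNAs, the overall signal and the spike-in signal were compared by a two-sided exact permutation test over all 70 allocations of the arrays. The labels pair no samples, and arrays were paired by position only in the alternative with the slide column as a block, where each column holds 1 array of each group. Tables were read with the R package data.table (1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

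Of 21 miRNA lists, those with at least 3 tested members were tested with limma's camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 17 lists tested. The lists cover the LPS and NF-κB response; markers of red blood cells, leukocytes, endothelium and platelets, epithelium (miR-200 family), skin, kidney and intestine, liver, ciliated airway, striated muscle, smooth muscle and mesenchyme, and neural cells; and the Sfmbt2 cluster, the miR-290 to miR-295 cluster, the Dlk1-Dio3 cluster, the H19 and miR-322 group, the let-7, miR-17-92, miR-15/16 and miR-30 families, and miRNAs numbered 1000 or above. Counts of members that passed are given over all tested miRNAs and adjusted over the list alone. Genomic clusters (probes within 10 kb) and seed-name families were tested in the same way as 22 further sets chosen after seeing the data.

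The groups, tests, filters, lists and alternatives were fixed before the data were examined, as was the rule for naming miRNAs. That rule names up to 12 miRNAs per direction with the largest change among those past the threshold whose groups do not overlap, those given as bounds, the 5 brightest of each group, up to 4 members of each list with the smallest p, and 6 miRNAs of general interest. Members named because they passed when adjusted over their list, and the further miRNAs singled out in the text, were chosen after their values were seen. The rule gave 84 miRNAs, of which 54 have a gene symbol in the gene table (GRCm38.p6) and 68 have a probe position on mm9 in the files.

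Alternatives covered scaling, background correction, the value table, the summary per miRNA, the floor, the filter, the test, the slide column as a block, a minimum fold of 2, and each array left out in turn. A fit without LPS replicates 2 and 4, a fit with array brightness as a covariate and the removal of the trend on probe GC content were added after seeing the data. The procedure was tested on simulated data with 470 miRNAs in 50 simulations, where it recovered 39.3% of changes of 1 log2 unit and 80.2% of changes of 2 log2 units, with 4.24% of calls false on average. Shifted lists were found in 100% and unshifted lists in 4% of simulations. The 4% cannot be carried over to the measured lists. In the real data, a split of the arrays other than the real one gave 11 of the 17 lists past camera's threshold. Nor can the 4.24% be carried over to the 23 miRNAs past the threshold. Another such split gave 14 miRNAs past it, against at most 2 in simulated data without changes. The number of arrays limits the precision of all values, and low signals near the floor compress differences.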

Results

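Amniotic fluid of pregnant mice was profiled for microRNAs (miRNAs) carried in exosomes, the small membrane vesicles that cells release. The series holds 8 single-colour Agilent mouse miRNA arrays, 1 per sample. The first group of 4 comes from mice that gave birth preterm after lipopolysaccharide (LPS, a component of the bacterial outer membrane that sets off inflammation) at 100 μg per kg on day 14 of pregnancy, with delivery about 48 h later. The other 4 come from cesarean sections and serve as the control, and the labels do not say whether these mice received an injection. Every sample is labelled day 17 of pregnancy, although LPS on day 14 with delivery about 48 h later would put delivery on an earlier day. The labels therefore do not settle whether the groups were of the same gestational age. Replicate numbers name the arrays in the order of deposition, which is also their column on the slide, and the labels pair no samples between the groups. The design asks which exosomal miRNAs differ between fluid of LPS-induced preterm birth and fluid taken at cesarean section.

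The arrays carried probes for 1881 mouse miRNAs, and between 405 and 554 of these were well above background on a given array. LPS arrays detected 458 ± 47.0 miRNAs (mean ± SD, n = 4) and cesarean arrays 480 ± 68.2 (n = 4), a difference smaller than the spread between arrays (two-sided exact permutation test, p = 0.657). Overall brightness, the log2 of the 75th percentile signal, was 8.06 ± 0.42 on LPS arrays and 8.20 ± 0.51 on cesarean arrays (n = 4 each, exact p = 0.743). The spike-in probes, which bind RNA added in equal amount to every array, read 10.87 ± 0.09 and 10.89 ± 0.05 (exact p = 0.743). The smallest p this design can reach in such a test is 0.0286. All 8 arrays lay on 1 slide, with the LPS arrays in one row and the cesarean arrays in the other, so the row and the group cannot be told apart.

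The probes with the strongest signals were mostly the same in both groups. Signals of different probes do not rank the miRNAs by abundance. The probes of miR-3963, miR-5100, miR-451a, miR-3473b, miR-709 and miR-8110 gave the strongest signals, from 12.82 for miR-8110 to 15.79 for miR-3963 on LPS arrays (mean log2, n = 4), and none of the 6 passed the test between the groups. The red blood cell miRNA miR-451a was the one well-known cell marker among them, at 14.34 ± 0.50 on LPS arrays and 13.35 ± 0.40 on cesarean arrays (SD, n = 4 each; limma adjusted p = 0.0814). Of the 6, only the miR-451a probe has a position on the genome build mm9.

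In exosomes from LPS-induced preterm birth, several epithelial miRNAs were higher, and miR-181b-5p and miR-181d-5p were lower, than at cesarean section. The miRNAs miR-200a-3p, miR-200b-3p and miR-200c-3p, which keep cells in an epithelial state, rose 2.35-fold, 2.11-fold and 2.68-fold, and miR-192-5p and miR-194-5p, a pair enriched in kidney and intestine, rose 2.29-fold and, by its brighter probe, 4.54-fold (n = 4 per group). miR-196a-5p, listed with that pair as a kidney and intestine marker, fell 2.35-fold. As lists, the kidney and intestine markers and the skin markers did not pass camera, and the miR-200 family passed it only at the preset correlation. The inflammation-induced miR-155-5p rose 2.13-fold and the leukocyte miRNA miR-142a-3p rose 2.34-fold. The erythroid miR-144-3p was at least 2.20-fold higher, being well above background on all 4 LPS arrays and on 0 of the 4 cesarean arrays, a bound that rests on the floor (log2 difference 0.14 with a floor 2 times as high). miR-181b-5p was 3.10-fold lower and miR-181d-5p 2.62-fold lower, and the neural miRNA miR-9-3p was also lower, at a level that only 1 of the 4 LPS arrays measured above background.

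Of the 470 miRNAs tested, 23 passed a Benjamini-Hochberg adjusted p of 0.05 in limma, 12 higher and 11 lower with LPS. At an unadjusted p of 0.05, 118 passed, 65 higher and 53 lower. The 4 LPS arrays lay entirely to one side of the 4 cesarean arrays for 80 miRNAs (17.0%), and this held for all 23 that passed. Chance gives 2.86% for a single miRNA not chosen by group. The filter used the groups and the miRNAs are correlated, so the 17.0% cannot be tested against that value. A small p with 4 against 4 arrays makes such separation likely, so it adds no separate support for the 23. The absolute log2 differences of the 23 ran from 0.89 to 3.34 with a median of 1.25. Of the 23, 21 had 2 or more probes above background, and in each of these 21 all such probes differed in the same direction. Sizes differed for some, as for miR-196a-5p (from -1.43 to -0.77). The probes of a miRNA read the same RNA in the same samples, so this agreement says nothing of effects of sample, slide row or labelling.

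Among the miRNAs that rose, miR-194-5p had a log2 difference of 2.18 ± 0.32 (SE; adjusted p = 0.0107) by its brighter probe, from 4.30 ± 0.53 on cesarean to 6.49 ± 0.43 on LPS arrays (SD, n = 4 each). Its other probe gave 1.14, and normexp background correction gave 0.83. The growth-linked miR-322-5p, the mouse counterpart of human miR-424, was among the bright ones and rose from 8.59 ± 0.46 to 10.42 ± 0.60 (difference 1.83 ± 0.35 SE, adjusted p = 0.0268), and both of its probes gave 1.83. Its X-linked neighbour miR-542-5p rose by 1.59 ± 0.37 (adjusted p = 0.0378), with probes from 0.96 to 1.59. miR-200c-3p rose by 1.42 ± 0.23 (adjusted p = 0.0107), let-7d-5p by 1.30 ± 0.27 (adjusted p = 0.0293) and miR-155-5p by 1.09 ± 0.24 (adjusted p = 0.0325). The smallest rise was that of miR-23b-3p, 1.86-fold.

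Among the miRNAs that fell, miR-181b-5p went from 6.73 ± 0.27 on cesarean to 5.09 ± 0.37 on LPS arrays (SD, n = 4 each), a log2 difference of -1.63 ± 0.26 (SE; adjusted p = 0.0107). miR-7667-3p differed by -1.41 ± 0.20 (adjusted p = 0.0107) and was well above background on 1 of the 4 LPS arrays. Its other 3 LPS arrays lay at the floor, so its SE and adjusted p do not measure the spread between LPS samples. The smallest difference of miR-7667-3p over the alternatives was -0.22. miR-9-3p had the largest difference, -3.34 ± 0.74 (adjusted p = 0.0325), but 3 LPS arrays sat at the floor of 3.75 and cesarean replicate 1, at 9.97, stood above the other cesarean arrays, which ran from 6.45 to 6.97. Without that array the difference was -2.51. The SE of miR-9-3p does not fully measure the spread between LPS samples either, as it rests on values at the floor. The others that fell were miR-1931, miR-181d-5p, miR-652-5p, miR-3059-3p, miR-218-5p, miR-196a-5p, miR-7075-5p and miR-6974-5p, between 2.06-fold for miR-6974-5p and 2.65-fold for miR-1931, with miR-218-5p well above background on 2 of the 4 LPS arrays.

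**Figure D1:**
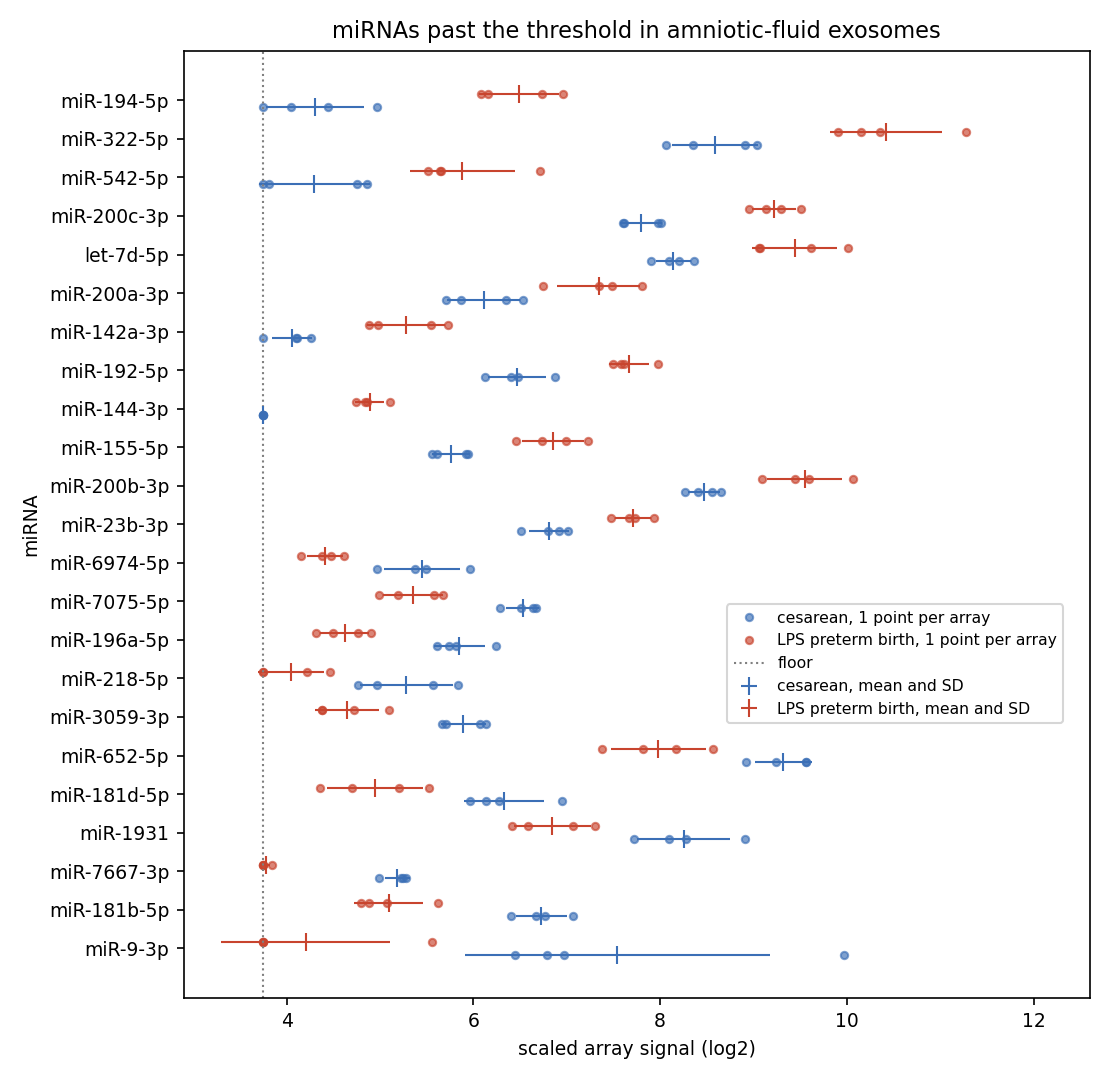
Scaled array signal (log2, x axis) of the 23 miRNAs past the threshold (y axis), with 1 point per array, ticks for the group means and horizontal bars for 1 SD, cesarean in blue and LPS preterm birth in red. The groups do not overlap in any of the 23, and the dotted line marks the floor at 3.75, where all 4 cesarean arrays of miR-144-3p, 3 LPS arrays each of miR-9-3p and miR-7667-3p, 2 LPS arrays of miR-218-5p and 1 cesarean array each of miR-194-5p, miR-142a-3p and miR-542-5p lie.

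Leaving out a single array moved the count of 23 to 5, 4, 3 and 6 without cesarean replicates 1, 2, 3 and 4, to 72, 6 and 5 without LPS replicates 1, 2 and 3, and to 28 without LPS replicate 4. It was 1 without scaling between arrays, 1 when scaled to the spike-in probes, and 1 with the slide column as a block, while the direction of all 23 was kept in each of these fits. With normexp background correction, 13 of the 23 moved toward 0 by more than 1.5-fold, among them miR-181b-5p (to -0.77), miR-181d-5p (to -0.59) and miR-142a-3p (to 0.31), while the 3 miR-200 members, miR-192-5p, miR-155-5p, miR-322-5p, let-7d-5p, miR-23b-3p, miR-1931 and miR-652-5p moved less. This correction adds an offset of 50 to every signal, which by itself compresses the differences of dim miRNAs. Such moves therefore do not show which differences are real. Without scaling, as with scaling to the spike-in probes, the median difference of all miRNAs was -0.20, against -0.06 in the scaled data, and all p-values measure only the spread between these samples, as the labels do not say that each came from a separate animal.

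On the genome build mm9 used by the files, the probes of the epithelial miRNAs lie in separate clusters. Those of miR-200a-3p (155429063 to 155429079) and miR-200b-3p (155429840 to 155429855) map to chromosome 4, and that of miR-200c-3p to chromosome 6 at 124668392 to 124668406. The miR-192-5p probe maps to chromosome 19 at 6264860 to 6264877, beside a copy of miR-194-5p at 6264664 to 6264679, and the miR-194-5p probe also matches chromosome 1 at 187137210 to 187137225, so the array does not tell these copies apart. The miR-155-5p probe lies on chromosome 16 at 84714394 to 84714410, within the host gene Mir155hg, and the miR-322-5p probe on chromosome X at 50407455 to 50407475, within C430049B03Rik. The probe of miR-23b-3p lies on chromosome 13 at 63401842 to 63401857 within Aopep, and that of miR-652-5p on chromosome X at 139173574 to 139173586 within Tmem164. Probes of miR-181b-5p match chromosome 1 and chromosome 2, and those of miR-9-3p match 3 loci on chromosomes 3, 7 and 13.

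Of the 21 miRNA lists, 17 had at least 3 tested members. By limma's camera with its preset correlation, 7 lists passed an adjusted p of 0.05, 6 of them higher with LPS and 1 lower. None of the 17 passed when camera estimated the correlation between members, with a smallest adjusted p of 0.364. By fry, which asks whether the members of a list move one way on balance, 4 lists passed, and 8 passed its test for change in either direction.

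All 5 members of the miR-200 family were higher on LPS arrays, with a median log2 difference of 1.23. Of these, 3 rose over all miRNAs tested and 5 rose when adjusted over the list alone. The remaining members, miR-141-3p (2.83-fold) and miR-429-3p (1.89-fold), had adjusted p-values of 0.0567 and 0.0513 over all miRNAs. The list passed camera (adjusted p = 5.65e-05, and adjusted p = 0.370 with an estimated correlation) and fry (adjusted p = 0.00664). Its mean on LPS replicate 4 was 7.60, against 8.20 to 8.28 on the other LPS arrays and 6.54 to 7.09 on the cesarean arrays.

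Kidney and intestine markers went both ways. miR-192-5p and miR-194-5p rose and miR-196a-5p, a Hox-cluster miRNA, fell, while adjusted over the list alone 3 rose and 1 fell. miR-215-5p, a relative of miR-192, was not well above background on any cesarean array and at least 1.98-fold higher on LPS arrays (adjusted p = 0.0771), a bound that also rests on the floor (log2 difference 0.25 with a floor 2 times as high). The list of 5 had a median of 0.99 and passed fry (adjusted p = 0.0261) but not camera (adjusted p = 0.0798). Skin and squamous markers had a median of 0.72 (camera adjusted p = 0.304), with miR-203-3p at 1.49 ± 0.75, miR-31-5p at 0.72 ± 0.36 and miR-205-5p at -0.17 ± 0.63 (SE).

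Erythroid markers were higher with LPS on all 3 tested members. The median log2 difference was 0.99, made up of miR-451a (0.99 ± 0.31 SE), miR-486a-5p (0.83 ± 0.35) and miR-144-3p. Over all miRNAs 1 of the 3 passed, and all 3 rose when adjusted over the list alone. The list passed camera (adjusted p = 0.00712, and adjusted p = 0.364 with an estimated correlation) and fry (adjusted p = 0.00664). Leukocyte markers did not pass as a list (median 0.09, camera adjusted p = 0.466): miR-142a-3p rose, while the neutrophil miRNA miR-223-3p differed by 0.09 ± 0.25 and the lymphocyte-enriched miR-342-3p by -0.45 ± 0.30 (SE). Of the endothelial and platelet markers, miR-126a-3p differed by -0.09 ± 0.30 and miR-24-3p by 0.23 ± 0.26.

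The 14 measured miRNAs of the LPS and NF-κB response went in both directions. miR-155-5p rose and miR-181b-5p fell over all miRNAs tested, and 3 rose and 3 fell when adjusted over the list alone. The added members are miR-146a-5p (0.79 ± 0.26 SE), a brake on NF-κB signalling, and miR-222-3p (0.78) on the higher side, and miR-146b-5p (-1.46 ± 0.42, but 0.49 by the scanner software's total per miRNA) and miR-125b-5p (-0.95 ± 0.29) on the lower side. miR-21a-5p, bright in both groups, differed by 0.36 ± 0.29 (adjusted p = 0.476). The list's median was 0.09 and its mean -0.03, so these differ in sign, and camera gave an adjusted p of 0.732 and fry's test for change in either direction 9.31e-06.

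miRNAs of growth and development made up most of the other lists that passed camera. The H19 and miR-322 list had a median of 0.88 over 7 members (camera adjusted p = 0.00712, and adjusted p = 0.496 with an estimated correlation): miR-322-5p rose over all miRNAs, and 4 rose when adjusted over the list alone, among them miR-542-3p (1.07 ± 0.29 SE) and miR-450a-5p (1.16 ± 0.35). The 1 tested miRNA made from H19 itself, miR-675-3p, differed by -0.55 (adjusted p = 0.343), so the rises lay among the X-linked miR-322 group. With only miRNAs detected on all 8 arrays, which left 3 members, its camera adjusted p was 0.225, in a range of 1.35e-08 to 0.225 over its alternatives. The let-7 family, which limits growth, had a median of 0.62 over 9 members (camera adjusted p = 0.00126, and adjusted p = 0.496 with an estimated correlation; fry adjusted p = 0.0445). let-7d-5p rose over all miRNAs and 3 members rose when adjusted over the list alone, with let-7f-5p at 1.12 ± 0.34 and let-7i-5p at 0.87 ± 0.25 beside it, while let-7b-5p differed by 0.09 ± 0.25 (-0.06 without scaling). The imprinted Dlk1-Dio3 cluster had a median of 0.33 over 26 members (camera adjusted p = 0.0175, and adjusted p = 0.591 with an estimated correlation), led by miR-434-3p (0.98 ± 0.26) and miR-136-5p (0.88 ± 0.22), the 2 that rose when adjusted over the list alone. Its median was 0.21 and its camera adjusted p 0.0706 without cesarean replicate 3, and they were 0.07 and 0.279 without LPS replicate 3, in a range of 1.43e-12 to 0.279 over its alternatives.

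The list of the placental Sfmbt2 intron cluster had a median of 1.06 over 18 members (camera adjusted p = 7.18e-05, and adjusted p = 0.496 with an estimated correlation). Its members were taken by name (the miR-297, miR-466, miR-467 and miR-669 families), not by genome position. Some probes, such as those of miR-466f-3p and miR-466i-5p, consist mostly or wholly of repeated GT or CA bases. The shift therefore cannot be credited to this locus alone. No member passed limma over all miRNAs or over the list alone, and 8 were higher at an unadjusted p of 0.05. The shift lay mostly in a pair of arrays: relative to the cesarean mean the list stood at 2.31 on LPS replicate 2 and 1.17 on LPS replicate 4, but at -0.05 and 0.40 on LPS replicates 1 and 3. Without LPS replicates 2 and 4, an alternative chosen after seeing the data, the adjusted p was 0.0826, in a range of 1.76e-06 to 0.0826 over its alternatives. The miR-290 to miR-295 cluster of the early embryo had a median of -0.14 (camera adjusted p = 0.635).

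Muscle and liver miRNAs separated the LPS arrays from one another. The striated muscle markers miR-1a-3p, miR-133a-3p, miR-133b-3p and miR-206-3p had a median difference of 0.26 (camera adjusted p = 0.669), but their mean relative to cesarean was 1.40 and 2.20 on LPS replicates 1 and 3 and -1.40 and -1.14 on LPS replicates 2 and 4. miR-122-5p, made by liver cells, differed by 2.30 ± 1.07 (SE; adjusted p = 0.211), at 8.27 and 9.81 on LPS replicates 1 and 3 against 5.04 and 5.56 on LPS replicates 2 and 4. The skin markers stood at 2.05 and 1.17 on LPS replicates 1 and 3 and at -0.14 and -0.35 on LPS replicates 2 and 4. Correlations between LPS arrays over the tested miRNAs ran from 0.836 to 0.959, and those between cesarean arrays from 0.938 to 0.976. Pairs of arrays from different groups ran from 0.845 to 0.956, with a median of 0.896 against 0.914 within LPS. LPS replicate 1 correlated more closely with cesarean replicate 2 (0.956) than with any other LPS array (0.945 at most, with LPS replicate 3).

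**Figure D2:**
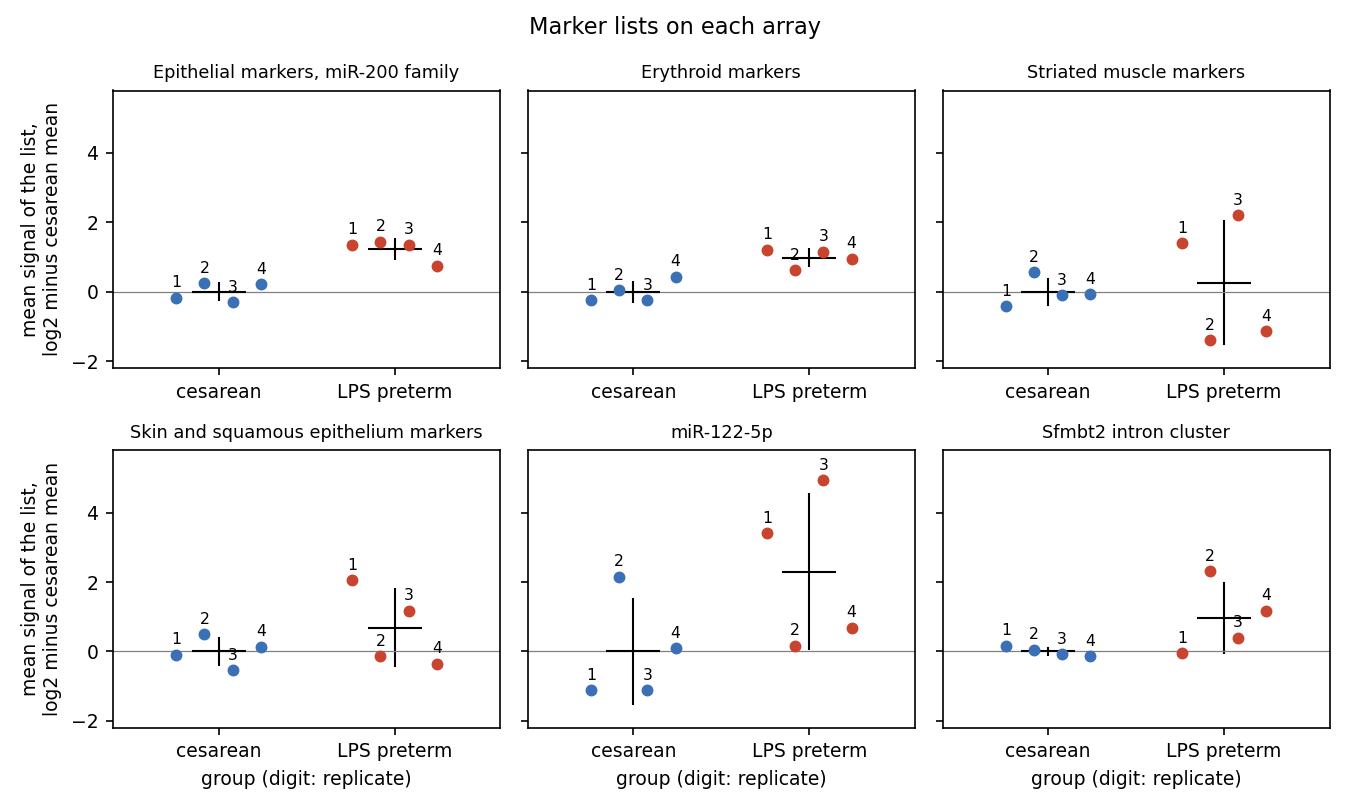
Mean log2 signal of each marker list on each array, minus the cesarean mean (y axis), by group (x axis), with 1 point per array, replicate digits above the points, and black marks for the group mean with 1 SD. The list means of the miR-200 family and erythroid markers lie above every cesarean array on all 4 LPS arrays. Of the erythroid markers, miR-451a and miR-486a-5p each overlap between the groups (13.76 and 7.47 on LPS replicate 2, 13.92 and 8.13 on cesarean replicate 4). Muscle, skin and miR-122-5p are highest on LPS replicates 1 and 3 and the Sfmbt2 cluster list, taken by name, on LPS replicates 2 and 4.

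Mesenchyme miRNAs split within their list. Adjusted over the list alone 4 fell, namely miR-199a-5p, miR-199a-3p, miR-199b-5p and miR-214-3p, and 1 rose, the smooth muscle miRNA miR-145a-5p (0.71). None passed limma over all miRNAs, where 1 was higher and 4 were lower at an unadjusted p of 0.05, with miR-214-3p at -1.34 ± 0.37 and miR-199a-5p at -1.03 ± 0.28 (SE). The list of 6 had a median of -0.93 (camera adjusted p = 0.163), and fry's test for change in either direction gave 0.0243. Neural markers were measured on miR-9-3p and on miR-128-3p, which differed by -0.26 ± 0.54 (SE). The ciliated airway markers had 0 tested members.

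The miR-17-92 clusters, which promote proliferation, had a median of -0.52 over 10 members, for example miR-18a-5p at -1.17 ± 0.41 and miR-20b-5p at -0.69 ± 0.32 (SE). The list did not pass camera (adjusted p = 0.0501, and adjusted p = 0.591 with an estimated correlation) or fry (adjusted p = 0.317). Its median stayed below 0 in all 26 alternatives, which reuse the same arrays, and it passed camera in 9 of them. The list mean relative to cesarean ran from -0.79 to -0.24 on LPS arrays and from -0.78 to 0.64 on cesarean arrays, so the groups overlapped. The miR-15/16 family had a median of 0.32 (camera adjusted p = 0.398) and the miR-30 family one of 0.32 (camera adjusted p = 0.163).

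Later-numbered miRNAs, those numbered 1000 or above, were lower as a group on LPS arrays. Their median log2 difference was -0.24 over 208 members, against 0.10 over the 262 others (camera adjusted p = 6.14e-06, and adjusted p = 0.496 with an estimated correlation). The 5 that fell over all miRNAs were miR-7667-3p, miR-1931, miR-3059-3p, miR-7075-5p and miR-6974-5p, and 3 fell when adjusted over the list alone. The probes of this group are richer in G and C bases, with a median of 64.3% against 50% for the others, and the list's mean relative to cesarean was -0.49 and -0.45 on LPS replicates 1 and 3 but -0.06 and 0.13 on LPS replicates 2 and 4.

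**Figure D3:**
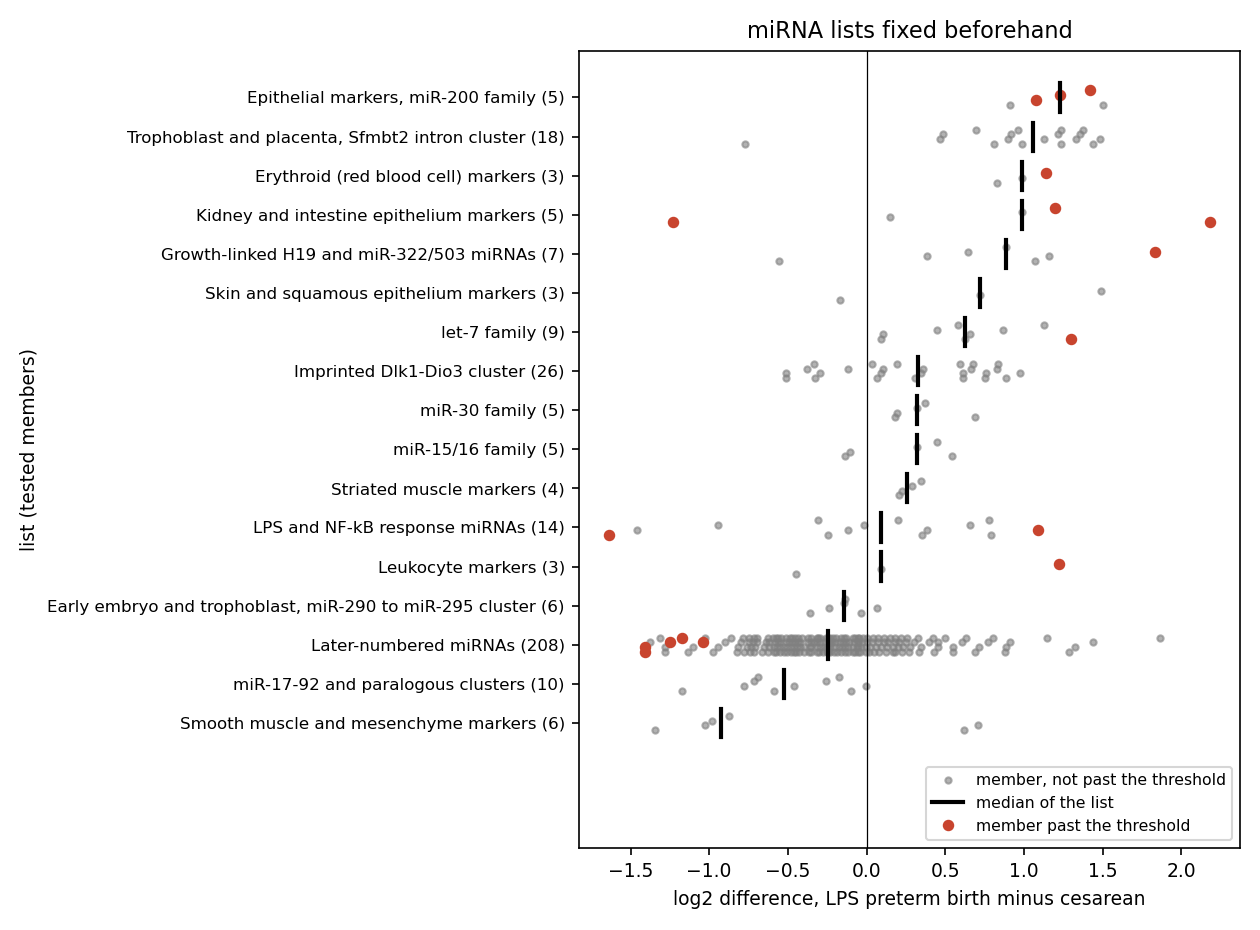
Log2 difference between LPS preterm birth and cesarean (x axis) of each tested member of the 17 lists (y axis, tested members in brackets), with members past the threshold over all miRNAs in red, others in grey, and black bars for the list medians. The miR-200 family has the highest median, 1.23, and the smooth muscle and mesenchyme list the lowest, -0.93.

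**Figure D4:**
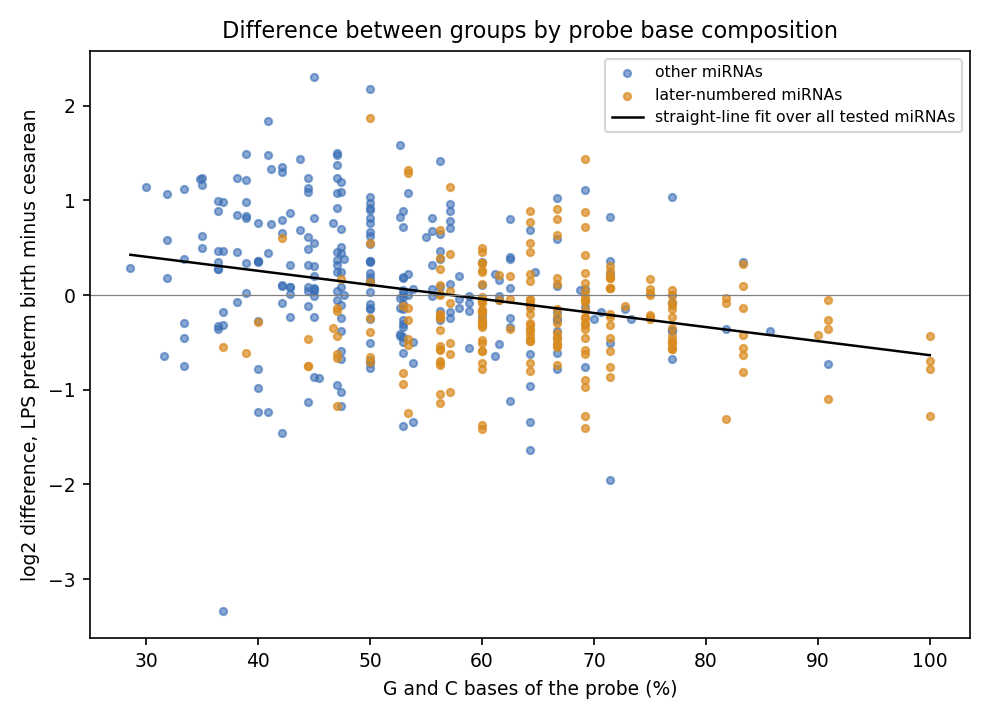
Log2 difference between LPS preterm birth and cesarean (y axis) against the GC content of the probe in percent (x axis), with 1 point per tested miRNA. The difference fell by 0.148 per 10 points of GC, and the later-numbered miRNAs lie to the right of the others, with median GC of 64.3% against 50%.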

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

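The split test on the miRNA lists and the comparison of mr_1 were chosen only after the result was seen, and the brightness covariate and the removal of the GC trend were added after seeing the data. Of 180 groups of 4 values tested for a single array far from the other 3, 6 had one, and chance alone gives about 1 in 20. miR-486a-5p was low on LPS replicate 2 (log2 7.47, against 8.36 to 8.55 on the other LPS arrays), and miR-17-5p was low on LPS replicate 4 (4.15, against 4.76 to 4.79). miR-497a-5p was high on LPS replicate 1 (8.04, against 7.38 to 7.43). On cesarean replicate 3, miR-291a-3p (5.39, against 5.97 to 5.98) and let-7i-5p (8.47, against 9.05 to 9.17) were low. The mean of the miR-200 list was low on LPS replicate 4 (7.60, against 8.20 to 8.28). The control probes hur_6, which no comparison used, had a mean scaled signal of 1275 on LPS arrays, above the cesarean range of 145 to 798. That mean came from LPS replicate 2 at 4028, and the exact permutation test between the groups gave p = 0.514. The control probes mr_1, also used in no comparison, were lower on LPS arrays (1999 to 2771) than on cesarean arrays (2900 to 4067), a log2 difference of -0.48 with an exact permutation p of 0.0286, and -0.62 with p = 0.143 before scaling. What the hur_6 and mr_1 probes detect is not given in the sources used here.

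The first pattern weighed is the set of 23 miRNAs past the threshold. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many, and the highest other split gave 14. That share of 0.0286 is the smallest this test can give, so it argues against chance for this count but cannot exclude it. With array brightness as a covariate the median absolute log2 difference of the 23 was 1.28 (1.25 without it). The signals had already been divided by this brightness, which differed little between the groups (8.06 on LPS and 8.20 on cesarean arrays). The covariate could therefore hardly have lowered the difference, and its result does not decide on brightness. The largest difference of a spike-in probe was 0.0744 and the smallest among the 23 was 0.893, but scaling removes an effect on all probes alike and 8 spike-in probes say nothing of effects on other probes, so the limit set beforehand for this test was too wide. Hybridization, scanning and other handling that followed the slide rows, to which the lower mr_1 signal may also belong, cannot be told apart from the groups, since each row holds 1 group. For the miRNA lists past camera, 9 of the 35 splits gave as many as the real 7 and the highest other gave 11, so chance cannot be excluded for that count.

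The second pattern is the higher level on LPS arrays of the miR-200 family and, among the kidney and intestine markers, of miR-192-5p and miR-194-5p, while miR-196a-5p of that list fell. Over all 10 members of both lists, removing the trend on probe GC left a median log2 difference of 0.928 (1.14 before), with quartiles of 0.68 and 1.22, which argues against base composition as the whole cause. A smaller share of one other source raises the markers of every other cell type alike, but the 15 markers of muscle, mesenchyme, endothelium, platelets and skin had a median of 0.227 and an upper quartile of 0.48, below the lower quartile of 0.933 of the 10 epithelial members. With markers of red blood cells, leukocytes, liver and neural cells added after the result was seen, 24 markers had a median of 0.23 and an upper quartile of 0.75, although the erythroid list (median 0.99) and miR-122-5p (2.30) were as high as the epithelial members. Skin and squamous markers had a median of 0.722, against a lower quartile of 1.08 in the miR-200 family, with 3 markers that differed widely between arrays, so more RNA from epithelial cells in general cannot be told apart from a change in these miRNAs with LPS or preterm labour, which was not tested.

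The third pattern is the lower level of later-numbered miRNAs on LPS arrays. The difference in medians between these and the other miRNAs was -0.35, and it was -0.168 after removing the trend on probe GC, so base composition of the probes may account for part of it. Among miRNAs well above background on all 8 arrays the difference was -0.377, which argues against signals close to the background. A biological cause of the remaining difference was not tested.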

How the results depend on the processing

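Brightness as a covariate, the fit without LPS replicates 2 and 4 and the check of slide columns were chosen after seeing the data. The 23 miRNAs past the threshold (12 higher, 11 lower) kept their direction in every alternative that tested them, but their number changed. It was 14 (5 lower) when scaled to the percentile of all probes, 37 (24 higher) with quantile normalization, 15 (5 lower) with normexp background and 6 (4 higher, 2 lower) with the scanner software's total per miRNA. It was 1 (0 higher, 1 lower) without scaling, 1 (0 higher, 1 lower) when scaled to spike-in probes and 1 (0 higher, 1 lower) with the slide column as a block, where 56, 53 and 83 passed limma unadjusted. With no filter, which tested 1881 miRNAs, it was 2 (1 higher, 1 lower), and 14 lists passed camera. Among miRNAs detected on all 8 arrays it was 15 (7 higher) of 338 tested. Array weights gave 52 (29 higher, 23 lower), and brightness as a covariate 14 (6 lower). The value table as deposited gave 19 higher, and a floor at 2 times the height 7 lower. The filter by the scanner software's detection call gave 26 of 558 tested, so the number past the threshold did not simply follow the number tested. The cause of these changes was not tested.

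With 1 array left out the total ran from 3 to 72, the higher from 1 to 37 and the lower from 2 to 35, the lowest total without cesarean replicate 3 and the highest without LPS replicate 1. The lists past camera ran from 7 to 8, the difference in detected miRNAs from -44.3 to 2.67 and that in overall signal from -0.35 to 0.05. Across 2250 values of named miRNAs, 1887 stayed on their side of the threshold, 292 no longer passed and 71 newly passed. Of these values 48 changed sign and 1 was at 0, and the 48 passed limma neither as reported nor in the alternative. Across 440 values of list medians, 411 stayed on their side of camera's threshold, 4 no longer passed, 25 newly passed, 11 changed sign without passing in either fit and 4 were at 0. The miR-200, let-7 and later-numbered lists passed in all 26 alternatives and the erythroid list in all 25 that tested it, each at the preset correlation. With an estimated correlation these 4 lists did not pass (adjusted p = 0.370, 0.496, 0.496 and 0.364). None of the miRNAs past the threshold passed in every alternative that tested it. miR-181b-5p passed in 23 of 27 alternatives, miR-200c-3p in 22 of 27 and miR-194-5p in 22 of 26. miR-192-5p passed in 17 of 27, miR-155-5p in 15, miR-200b-3p in 14, miR-196a-5p in 13, miR-200a-3p in 11 and miR-181d-5p in 10. Of 26 alternatives, miR-144-3p passed in 16, miR-9-3p in 12, miR-142a-3p in 11 and miR-218-5p in 2. No paired analysis by animal was possible because the labels pair no samples. The slide-column block paired arrays by position, but the deviations of arrays in the same column correlated between -0.491 and -0.194, and 0 of the 4 LPS arrays were closest to the cesarean array of their own column. Signals near the background limit what can be said of miR-9-3p, miR-7667-3p and miR-218-5p on the LPS arrays.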

Other observations

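The tests of clusters and families were chosen only after the data were seen. Of 22 sets, made of 12 genomic clusters and 10 families named alike, 8 passed camera, and none did with an estimated correlation (smallest adjusted p = 0.416). The miR-181-5p family, which tunes lymphocyte and vascular inflammatory signalling, was the one lower set among them, with a median log2 difference of -1.39 over 3 members (camera adjusted p = 0.00445, and adjusted p = 0.416 with an estimated correlation; fry adjusted p = 0.00886). miR-181b-5p and miR-181d-5p fell, and miR-181a-5p differed by -0.96 (adjusted p = 0.0567). The cluster that runs from miR-431-5p to miR-136-3p in the imprinted Dlk1-Dio3 region had a median of 0.59 over 5 members (camera adjusted p = 0.0146, and adjusted p = 0.416 with an estimated correlation). The sensory-organ and epithelial cluster of miR-182, miR-96 and miR-183 had a median of 1.09 (camera adjusted p = 0.0572).

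The first principal component of the tested miRNAs held 45.3% of the variance and set LPS replicates 2 and 4 (15.3 and 12.1) apart from the other arrays, which ran from -11.1 to 0.25. The second held 29.6%, with LPS replicates 1 and 3 at 10.2 and 9.20, LPS replicates 2 and 4 at 4.35 and -0.02, and cesarean arrays from -9.66 to -0.77. miR-3472 had a loading of 0.188 on the first component, among the strongest on the side of LPS replicates 2 and 4. Members of the Sfmbt2 list also lay there, while miR-205-5p, miR-206-3p and miR-1a-3p lay on the other side.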
